A study of Mus musculus with 8 samples.

How the data were processed

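RNA was sequenced from CD8 T cells sorted from the livers of male C57BL/6J mice. Per the labels' protocols, mice aged 6 weeks received an agonist antibody against CD137, a costimulatory receptor of T cells, on day 0, 3 and 6, and livers were taken on day 8. The sort gate kept live CD45+ MHC class II- NK1.1- TCRβ+ CD8α+ CD4- cells that were KLRG1+ and CD127-, a surface profile of effector cells. These were parted by surface CD11c into a CD11c+ and a CD11c- subset, with 4 libraries each. The labels number the libraries 1 to 4 within each subset and do not say whether they came from separate mice, so p-values measure the spread between these samples, which may be technical.

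Per the labels' protocols, RNA was column-purified, amplified with a modified SMART-seq2 protocol (10 to 12 cycles of preamplification), made into libraries with Nextera XT and read as single reads of 50 bp. Per the submitters' processing notes, the tools were bcl2fastq, TopHat2 2.0.8b and HTSeq, with the mouse build mm9. The gene annotation and the strand setting of the counting are not given in the sources used here. The deposited files hold raw read counts per gene symbol, 1 file per library, with no normalization. Each has 22609 gene rows and 5 summary rows, which stayed out of library sizes and tests. Of uniquely placed reads, 65.1% ± 1.66 (SD, n = 8) fell in no annotated gene and 0.182% ± 0.0104 were ambiguous between genes. Alignments at more than 1 place made up 52.0% ± 1.07 of the sum of all rows. As such reads were not assigned, genes with near-identical copies (Ly6c2, the Klr, Gzm and H2 families, ribosomal proteins) carry uncertain absolute levels. Without a stated strand setting, overlapping and antisense genes cannot be told apart.

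Gene reads ranged from 5090345 to 7093163 per library, and genes with at least 1 read from 10482 to 12581. Before averaging, every pair of libraries of a subset was compared by chi-square over genes with at least 10 reads. The lowest value per degree of freedom was 9.43, so no pair differed by read sampling alone and each library counts as 1 sample. This does not tell separate samples from separately amplified parts of the same sample.

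Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest with default settings), as CD11c+ minus CD11c-, with Benjamini-Hochberg adjustment over 10073 tested genes and a threshold of 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the root of the F statistic. CPM are gene counts scaled by library size and TMM factors to the usual CPM unit and are given as mean ± SD over 4 libraries. In total, 39 gene lists were fixed before the data were examined. Of their 853 entries, 840 matched a symbol or an older symbol in the files and 13 did not. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. For each list the calls adjusted over the list alone are given beside those over all genes. The adjustment over the list alone was made within each list, with no correction over the 39 lists, some of which share genes. Its calls are therefore weaker than those over all genes.

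The rule for named genes, also fixed before the data were examined, took 4 sets. The first holds the genes of the sort and gate markers. The second holds up to 14 genes per direction past the threshold, with at least 10 CPM in the higher subset and no overlap between subsets, passing over unnamed models. The third holds, per list, up to 4 members past the threshold and up to 2 further members of highest mean CPM. The fourth holds genes that a count of 5 or fewer calls for. As 5 genes passed over all genes, list members that passed over the list alone, and further genes given with their values, were chosen after their values were seen. Of the 5 genes, 1 is not reported here.

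The steps were tested on simulated data drawn from the means, library sizes and dispersions of the real libraries, over 10073 genes with 200 changed per simulation and 5 simulations. The quasi-likelihood test recovered 6.21% of genes changed 1.5-fold, 35.6% of those changed 2-fold and 77.4% of those changed 4-fold, and 12 of 394 calls (3.05%) were false. A simulated list changed 1.25-fold was called with both correlations and no other list was. Genes were drawn independently of each other, so the simulation does not test list calls where members correlate. In the real libraries the estimated correlation was 0.286 for the ribosomal protein list, for example. Alternatives were RLE factors, library size only, no filter, a filter of at least 5 CPM in 4 libraries, a replicate block, each library or number left out, DESeq2 1.42.0, limma voom with quality weights, a test against 1.5-fold, and a threshold of 0.01. The other quasi-dispersion setting of edgeR (legacy=FALSE) and a fit without the 3 libraries with the fewest detected genes were added after seeing the data. Transcript length and GC content came from a GENCODE annotation of a later mouse build, matched by symbol for 9979 of the tested genes (99.1%), and no coordinates are given.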

Results

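The data were 8 RNA-seq libraries of intrahepatic KLRG1+CD127- CD8 T cells from mice treated with an agonist antibody against CD137, 4 from cells with surface CD11c and 4 from cells without it. CD11c is an integrin chain used mostly as a marker of dendritic cells and other myeloid cells, and is also found on some activated T cells. Libraries held a mean of 5809000 gene reads ± 659400 (SD, n = 8), and 10 genes took 10.3% ± 0.327 of them. The comparison asks which transcripts set the CD11c+ cells apart from CD11c- cells of the same liver gate.

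CD11c+ cells had more transcript of Itgax, Ly6c2 and Id2 and less of Cxcr5. Itgax, which encodes CD11c itself, was 24.3-fold higher, at 243 CPM ± 76.4 against 10.1 ± 5.64 (SD, n = 4 each). Ly6c2, a surface antigen of memory and effector CD8 T cells and of monocytes, was 2.65-fold higher (784 CPM ± 209 against 296 ± 68.2), and Id2, a transcriptional regulator that supports effector CD8 T cells, was 1.98-fold higher (625 ± 106 against 315 ± 29.6). Cxcr5, the receptor for the follicle chemokine CXCL13, was 4.41-fold lower (28.1 ± 12.5 against 124 ± 32.9). For each of these genes the 4 libraries of one subset lay above the 4 of the other.

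By edgeR's quasi-likelihood test, the log2 fold changes were 4.60 (SE 0.36, adjusted p = 0.000136) for Itgax, 1.40 (SE 0.20) for Ly6c2, 0.99 (SE 0.13) for Id2 and -2.14 (SE 0.30) for Cxcr5, the last 3 with adjusted p = 0.023. In all, 5 genes passed the threshold among 10073 tested, 3 higher and 2 lower, and 473 had an unadjusted p under 0.05 (245 higher, 228 lower). DESeq2 called 24 higher and 12 lower and limma voom with quality weights 14 higher and 5 lower, with all 5 genes among the calls of each. Itgax passed whichever library was left out, while Id2, Ly6c2 and Cxcr5 each lost the threshold in 6 or 7 of the 8 fits without 1 library, with adjusted p of 0.052 to 0.132 there. Without CD11c+ replicate 3 or CD11c- replicate 1, 3 or 4 all 3 of them lost it.

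**Figure D1:**
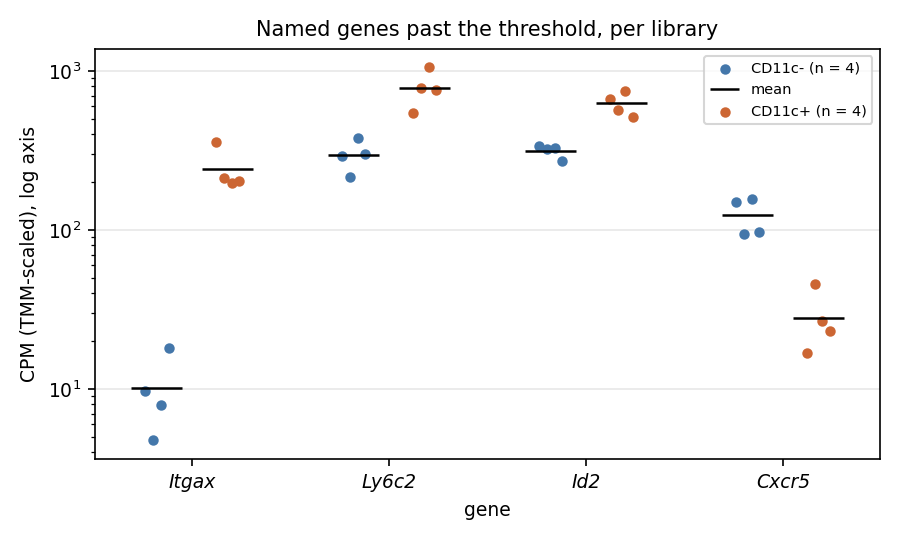
Expression of Itgax, Ly6c2, Id2 and Cxcr5, which passed the threshold, in each library, in TMM-scaled CPM on a log axis. Points are single libraries (4 per subset) and black lines are means. Itgax lay between 198 and 357 CPM in CD11c+ libraries and between 4.76 and 18.0 CPM in CD11c- libraries.

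The other genes of the sort gate differed by less. Klrg1 was at 534 CPM ± 61.4 and 454 ± 62.3 in CD11c+ and CD11c- cells, Cd8a at 1173 ± 70.6 and 1121 ± 86.0, Cd8b1 at 1397 ± 233 and 1199 ± 103, and Ptprc, which encodes CD45, at 2538 ± 279 and 2401 ± 229. The T cell receptor chains Cd3d (log2 fold change -0.23), Cd3e (0.03), Cd3g (-0.15) and Cd247 (-0.10) did not pass the test, with adjusted p from 0.991 to 0.995. Il7r, which encodes CD127, was low in both subsets, at 8.27 CPM ± 6.83 and 3.83 ± 2.38. Cd4 and Klrb1c, which encodes NK1.1, were under the expression filter, at no more than 1.56 and 8.99 CPM in any library. Tnfrsf9, the transcript of CD137, was at 352 CPM in both subsets, with SDs of 112 and 107. Of the 12 tested genes in the sort list, Itgax rose over all genes and 2 rose adjusted over the list alone, the second being H2-Ab1. The list was called higher by camera (adjusted p = 2.28e-06) and not with an estimated correlation (adjusted p = 0.148 with an estimated correlation). As it holds Itgax, the gene of the sorted protein, its call is not independent of the sort. Its median log2 fold change was 0.15 and its mean 0.74.

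Of 12 tested NK receptor genes, 4 rose adjusted over the list alone. Klre1 was 4.24-fold higher (57.2 CPM ± 27.0 against 13.5 ± 1.69), Klrc1, which encodes NKG2A, 3.46-fold (53.0 ± 11.03 against 15.4 ± 6.39), Klrk1, which encodes NKG2D, 2.75-fold (193 ± 38.7 against 70.1 ± 27.6) and Klrd1, which encodes CD94, the partner chain of NKG2A, 2.58-fold (208 ± 83.8 against 80.7 ± 16.3). Each was higher in all 4 CD11c+ libraries than in any CD11c- library. Of 12 tested members of the NK receptor list, 0 passed over all genes by edgeR's default setting (adjusted p from 0.0637 for Klre1 to 0.0992 for Klrd1), and these 4 rose adjusted over the list alone. The same 4 had an unadjusted p under 0.05, and were called by both DESeq2 and limma voom and by edgeR with legacy=FALSE, a setting chosen after seeing the data (adjusted p from 0.0175 to 0.0494). Another 6 members had positive log2 fold changes and 2 negative ones, so that the list had a median log2 fold change of 0.84 (0.53 without CD11c+ replicate 3, 1.37 without CD11c- replicate 3 and 1.55 with no filter). Camera called the list higher (adjusted p = 1.13e-10), and the call was lost with an estimated correlation (adjusted p = 0.0838 with an estimated correlation).

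Of the cytotoxic granule genes 4 rose adjusted over the list alone and none fell. Gzma (2.42-fold, 1324 CPM ± 367 against 548 ± 140) and Gzmb (1.79-fold, 1908 ± 389 against 1064 ± 151), both granule proteases, rose adjusted over the list alone, as did Gzmm (2.85-fold, 57.0 ± 25.2 against 20.0 ± 5.61) and Serpinb9, the inhibitor of granzyme B (1.42-fold, 646 ± 63.4 against 454 ± 29.4). Over all genes 0 of 17 tested members passed by edgeR's default setting, with adjusted p from 0.0637 for Gzmb and Gzma to 0.247 for Gzmm. An unadjusted p under 0.05 was found for 8, of which Gzmk and Rab27a were lower (log2 fold changes -0.22 and -0.30). Of the 17, 11 had positive and 6 negative log2 fold changes. DESeq2 called these 4 and limma voom called 3 of them, all but Gzmm. With legacy=FALSE edgeR called Gzma (adjusted p = 0.0172) and Gzmb (adjusted p = 0.0188). Prf1, which encodes perforin, was at 718 CPM ± 144 and 577 ± 71.7 and Gzmk at 1064 ± 87.8 and 1241 ± 103, and neither passed either adjustment. The list was called higher by camera (adjusted p = 0.000336), with a median log2 fold change of 0.10 (0.06 without CD11c+ replicate 3), and lost the call with an estimated correlation (adjusted p = 0.0838 with an estimated correlation). It was the only list called by the directional fry test (adjusted p = 0.0453).

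**Figure D2:**
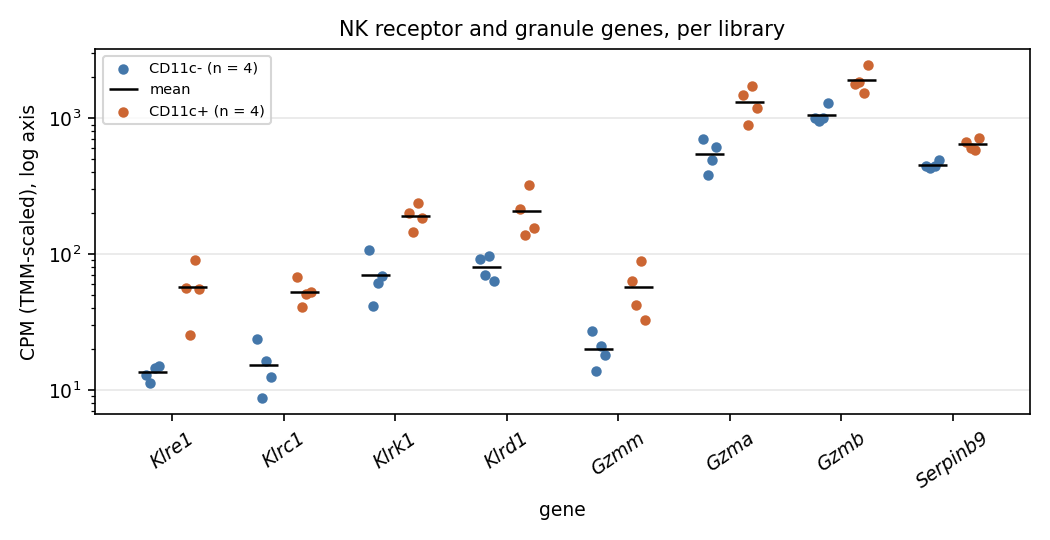
Expression of 4 NK receptor genes and 4 granule genes in each library, in TMM-scaled CPM on a log axis. Points are single libraries (4 per subset) and black lines are means. For each of the 8 genes the lowest CD11c+ library lay above the highest CD11c- library, as for Gzmb at 1534 and 1286 CPM.

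Of the NK and ILC1 markers, Eomes, which T cells also express, was at 183 CPM in CD11c+ and 177 in CD11c- cells. Ncr1, which encodes NKp46, was at 0.523 CPM in CD11c+ and 0.0941 in CD11c- libraries on average and at most 1.78 in any library. Tyrobp, an adaptor abundant in NK and myeloid cells, was at 24.0 CPM ± 22.4 and 11.4 ± 7.34, and Fcer1g at 13.7 ± 10.1 and 7.23 ± 7.38, both highest in CD11c+ replicate 3. Of 10 tested NK and ILC1 markers, 0 passed over all genes by edgeR (2 at an unadjusted p under 0.05) and Klre1 alone rose adjusted over the list alone, the 1 member also called by DESeq2 and limma voom. Camera called the list higher (adjusted p = 0.0257), a call lost with an estimated correlation (adjusted p = 0.455 with an estimated correlation) and without CD11c+ replicate 3 (adjusted p = 0.194) or 4 (adjusted p = 0.103).

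Terminal effector genes were led by Id2. It was the only one of 28 tested members to pass over all genes by edgeR's default setting, and 8 rose adjusted over the list alone. DESeq2 called Gzma, Gzmb, Id2, Tbx21 and Zeb2 and limma voom the same without Zeb2. Besides Id2, Gzmb and Gzma the 8 were the transcription factors Tbx21 (T-bet, 1.54-fold, 349 CPM ± 26.3 against 227 ± 19.0) and Zeb2 (2.67-fold, 43.7 ± 12.0 against 16.3 ± 4.74), the sphingosine phosphate receptor S1pr5 (2.31-fold), Anxa1 (5.16-fold, at 9.23 CPM ± 8.42 against 1.77 ± 1.10) and Fgl2 (1.39-fold). Over all genes the adjusted p by edgeR were 0.945 for S1pr5 and Anxa1 and 0.99 for Fgl2. Anxa1 had a log2 fold change of 2.37, and of 1.499 without CD11c+ replicate 3. Cx3cr1, a receptor of effector cells, was at 483 CPM ± 94.8 and 392 ± 37.8 and did not pass. Of the 28, 17 had positive and 11 negative log2 fold changes, with the abundant Anxa2 (-0.22) and S100a10 (-0.23) among the negative ones. Camera called the list higher (adjusted p = 2.8e-07) with a median log2 fold change of 0.09 (0.05 without CD11c- replicate 1 and 0.14 without CD11c+ replicate 4), and the call was lost with an estimated correlation (adjusted p = 0.0838 with an estimated correlation). Among 43 tested T cell transcription factors Id2 rose over all genes by edgeR (DESeq2 also called Tbx21, Tox2 and Zeb2, limma voom Tbx21 and Tox2), and Id2, Tbx21 and Zeb2 rose and Tox2 fell adjusted over the list alone. That list was not called by camera (adjusted p = 0.467).

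Of 25 tested naive and memory precursor genes 2 fell, Cxcr5 among them, both over all genes and adjusted over the list alone. Among members that did not pass were Tcf7, which encodes the transcription factor TCF-1 (55.4 CPM ± 25.1 against 111 ± 43.6, log2 fold change -1.01, adjusted p = 0.945), and, with the opposite sign, Il7r (log2 fold change 1.11). Of the 25, 17 had negative and 8 positive log2 fold changes, with a median of -0.29 (-0.19 without CD11c- replicate 1). Camera called the list lower (adjusted p = 8.94e-07), and not with an estimated correlation (adjusted p = 0.221 with an estimated correlation).

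Some chemokine and homing receptors differed, in opposite directions. Of 18 tested, Cxcr5 alone was called over all genes by edgeR and limma voom, and DESeq2 also called Ccr2. Adjusted over the list alone Cxcr5 fell and 4 rose, which were Ccr2 (2.30-fold, 456 CPM ± 125 against 199 ± 72.1), Ccr3 (10.0 ± 4.89 against 1.49 ± 1.23), the lysophospholipid receptor Gpr55 (16.1 ± 7.70 against 3.10 ± 3.02, log2 fold change 2.37, and 3.16 without CD11c- replicate 4) and S1pr5 (33.4 ± 10.0 against 14.4 ± 8.45). Camera did not call the list (adjusted p = 0.746), and its median log2 fold change was negative (-0.14, but 0.00 without CD11c+ replicate 1) while its mean was positive (0.17). Ccr2 and Ly6c2 are also among the monocyte and Kupffer cell markers, where they were the members that rose adjusted over the list alone, and Ly6c2 the only 1 of 11 called over all genes by edgeR and limma voom, with Ccr2 also called by DESeq2. That list was called higher (adjusted p = 0.0476; adjusted p = 0.496 with an estimated correlation), a call lost in 4 of the 8 fits without 1 library, while its myeloid member Lyz2 was at 115 CPM ± 110 and 82.6 ± 45.3.

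Of 22 tested inhibitory receptor and exhaustion genes, 0 passed over all genes by edgeR and 7 had an unadjusted p under 0.05, with Tox2 called by DESeq2 and limma voom. Adjusted over the list alone Tox2, a transcription factor of the TOX family, fell (26.4 CPM ± 9.25 against 63.5 ± 10.9) and the inhibitory receptor Lilrb4 rose (83.3 ± 27.0 against 40.1 ± 15.5). Pdcd1, which encodes PD-1, was at 472 ± 168 and 701 ± 154, Tigit at 318 ± 33.8 and 435 ± 79.9, Tox at 279 ± 90.0 and 434 ± 112 and Havcr2, which encodes TIM-3, at 310 ± 71.8 and 228 ± 60.4, and none of the 4 passed. Among 16 cytokines and chemokines, 0 passed over all genes (3 at an unadjusted p under 0.05), and Xcl1 (2.11-fold, 56.4 ± 13.5 against 26.7 ± 7.61) and Ccl4 (1.68-fold, 492 ± 110 against 293 ± 73.4) rose adjusted over the list alone and were called by DESeq2 but not limma voom. Ifng was at 101 ± 29.6 and 79.9 ± 35.8, Ccl3 at 238 ± 110 and 134 ± 71.7 and Ccl5 at 5584 ± 1368 and 6510 ± 948. Among 16 costimulatory receptor genes, 0 passed over all genes (6 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma voom), and Tnfsf14 (LIGHT, 2.05-fold) and Cd226 (DNAM-1, 1.57-fold) rose adjusted over the list alone. Of 13 genes of regulatory CD8 T cells, 0 passed over all genes (4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma voom), and Xcl1 and Fgl2 rose and Tnfrsf18 (140 ± 15.3 against 194 ± 34.9) and Il2rb (1532 ± 189 against 1902 ± 194) fell adjusted over the list alone. Camera called none of these 4 lists, with adjusted p from 0.13 to 0.656. The inhibitory list was called lower without the 3 libraries with the fewest detected genes (adjusted p = 0.000368) and without CD11c+ replicate 2, CD11c- replicate 1 or CD11c- replicate 4 (adjusted p = 0.00723, 0.0297 and 0.0497), and the cytokine list higher with the stricter filter (adjusted p = 0.0298).

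Of 40 tested genes of the G2 and M phases of the cell cycle, 37 had positive log2 fold changes, with a median of 0.20 (0.10 without the 3 libraries with the fewest detected genes), and 0 passed over all genes by edgeR, DESeq2 or limma voom, or adjusted over the list alone, while 9 had an unadjusted p under 0.05. Mki67, which encodes the proliferation antigen Ki-67, was at 548 CPM ± 74.4 and 409 ± 21.8, Top2a at 934 ± 113 and 741 ± 91.4, and Kif23 and Cenpe had log2 fold changes of 0.45 and 0.42. Camera called the list higher (adjusted p = 3.36e-08), and lost the call with an estimated correlation (adjusted p = 0.114 with an estimated correlation). The 36 tested S phase genes were not called (adjusted p = 0.81). Of 49 tested ribosomal protein genes 42 had negative log2 fold changes, with a median of -0.13, and 0 passed either adjustment by edgeR or were called by DESeq2 or limma voom (1 at an unadjusted p under 0.05). Camera called them lower (adjusted p = 0.00473; adjusted p = 0.613 with an estimated correlation), and not without the 3 libraries with the fewest detected genes (adjusted p = 0.819, median 0.03) and in 3 of the 8 fits without 1 library. Of 22 fatty acid oxidation genes, 0 passed either adjustment or were called by the other tools (1 at an unadjusted p under 0.05) and 17 had negative values, with a call lower (adjusted p = 0.038; adjusted p = 0.285 with an estimated correlation), which 6 of the 8 fits without 1 library lost.

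**Figure D3:**
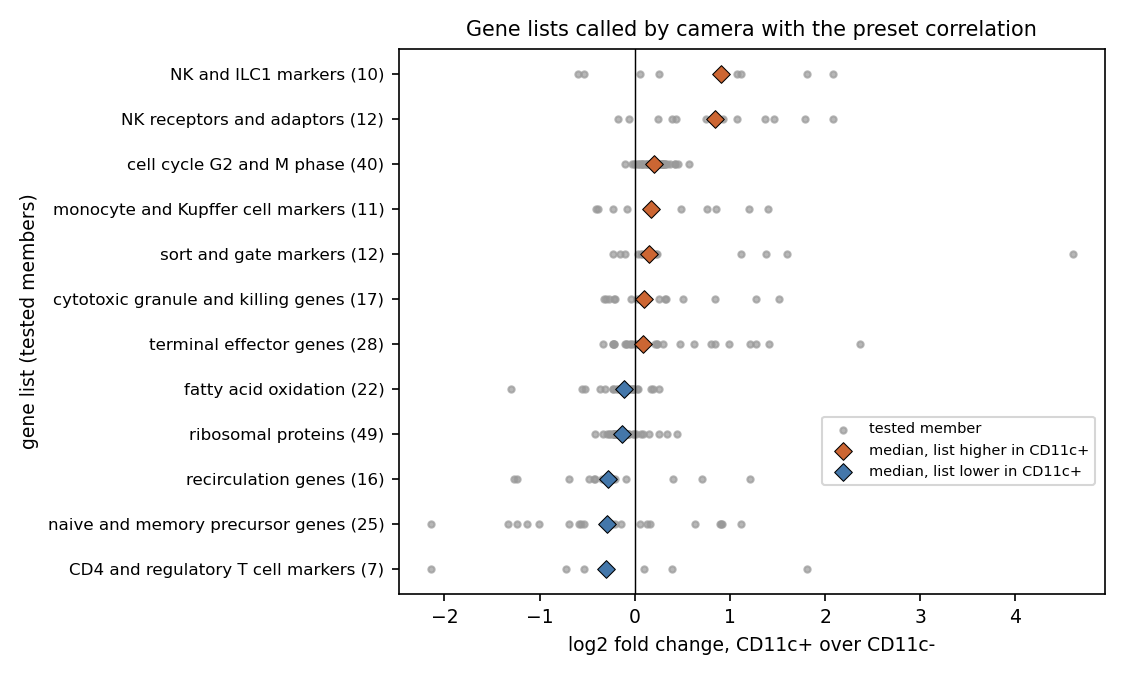
Log2 fold changes of the tested members of the 12 gene lists called by camera at the preset correlation. Grey points are genes, diamonds are list medians coloured by the direction of the call, and numbers in brackets are tested members. Medians ran from -0.30 to 0.90, and members of most lists lay on both sides of 0.

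Mouse T cells express MHC class II genes little, and the gate left out MHC class II+ cells by surface stain. The MHC class II list also holds Ctss, which was at 113.8 CPM or more in every library. Some genes of this list rose and others fell, but only adjusted over the list alone. Of 10 tested, 0 passed over all genes by edgeR, DESeq2 or limma voom, and 6 had an unadjusted p under 0.05. By edgeR the adjusted p of these 6 over all genes ran from 0.923 for H2-Ab1 and Cd74 to 0.991 for H2-Eb1. Adjusted over the list alone 4 rose, H2-Ab1 (2.60-fold, 51.3 CPM ± 20.5 against 19.8 ± 13.2), H2-Aa (3.03-fold, 31.8 ± 22.7 against 10.5 ± 5.98), H2-Eb1 (2.70-fold, 27.0 ± 21.3 against 10.0 ± 6.43, log2 fold change 1.43, and 0.78 without CD11c+ replicate 3) and the invariant chain Cd74 (2.09-fold, 81.0 ± 34.0 against 38.7 ± 16.1). H2-Ob (4.36 ± 1.12 against 12.6 ± 6.86) and Ctss (147 ± 25.9 against 192 ± 17.7) fell by the same adjustment. The 3 H2 genes that rose were highest in CD11c+ replicate 3, at 69.7, 59.3 and 56.1 CPM, as were Tyrobp at 55.2, Lyz2 at 265 and S100a8 at 153. Camera did not call the list (adjusted p = 0.13), and called it higher without the 3 libraries with the fewest detected genes (adjusted p = 1.16e-05) and without CD11c+ replicate 1, CD11c- replicate 1 or CD11c- replicate 4 (adjusted p = 0.0226, 0.0485 and 0.0497). The summed level of 8 dendritic cell markers was 11.2 CPM ± 8.09 in CD11c+ and 3.83 ± 2.63 in CD11c- libraries (exact permutation test, two-sided p = 0.257, with 0.0286 the smallest p possible). Of 7 tested dendritic cell markers Itgax alone rose, over all genes and adjusted over the list alone. Without a call by camera (adjusted p = 0.0765), their mean log2 fold change was 0.30 and their median -0.20 (-0.05 without CD11c+ replicate 1). The list, Itgax included, was called higher with no filter (18 tested, adjusted p = 0.00941, median 0.39), with the stricter filter (adjusted p = 0.000688), without the 3 libraries with the fewest detected genes (adjusted p = 0.0112) and in 3 of the 8 fits without 1 library.

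Few markers of other cells passed the test. Of 7 CD4 and regulatory T cell markers Cxcr5 alone fell, over all genes and adjusted over the list alone, with a camera call lower (adjusted p = 0.038; adjusted p = 0.455 with an estimated correlation) that no filter and 5 of the 8 fits without 1 library lost. Among 6 hepatocyte markers Ass1 fell adjusted over the list alone (13.9 CPM ± 3.20 against 26.1 ± 2.62), and among 4 endothelial and stellate cell markers Dnase1l3 did (47.9 ± 12.7 against 98.7 ± 17.3), with 0 of either past the threshold over all genes by edgeR. Each was the 1 member of its list with an unadjusted p under 0.05, and DESeq2 and limma voom called Dnase1l3 and not Ass1. By edgeR the adjusted p over all genes were 0.923 for Ass1 and 0.215 for Dnase1l3. The neutrophil transcript S100a8 was at 49.7 CPM ± 69.6 and 27.5 ± 24.1, and its highest values were in replicate 3 of both subsets, at 153 and 58.9 CPM. The haemoglobin transcript Beta-s was also highest there, at 91.2 and 83.9 CPM, against at most 11.2 in the other libraries. Among 35 lists tested, camera called 12 at the preset correlation, 7 higher and 5 lower, of which 1 is not described here, and 0 with an estimated correlation. Lists not called had adjusted p from 0.0662 to 0.832. Among them, heat shock and dissociation stress genes were called higher without CD11c+ replicate 1 (adjusted p = 0.00193), CD11c- replicate 2 (adjusted p = 0.0261) or CD11c- replicate 3 (adjusted p = 0.0381). After removing the trend on transcript length and GC content, camera called them (adjusted p = 0.0422) and dendritic cell markers (adjusted p = 0.0104) higher. That test used fold changes divided by their SE in place of the counts, so its calls cannot be credited to the trend alone. Hepatocyte markers were called lower without CD11c- replicate 1 (adjusted p = 0.0289), and neutrophil markers higher without the 3 libraries with the fewest detected genes (adjusted p = 0.00134). In 4 of the 35 splits of the libraries into 4 and 4, the real one included, at least 12 lists were called. No principal component separated the subsets, and component 1 (28.7% of the variance) and 2 (26.0%) set apart CD11c+ replicates 1 and 2 and CD11c- replicate 1, the 3 libraries with the fewest detected genes (10482, 10892 and 10783). Without them 9 genes were higher and 2 lower, and the newly called included Klre1, Klrk1, Klrc1, Klrd1 and Gzma.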

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

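The tests of dendritic cells and of NK cells were chosen after the results they measure were seen, the fit without the 3 libraries with the fewest detected genes was chosen after the data were seen, and the others before. In 154 groups of 4 values, 13 had a library far from the other 3. Chance gives about 7.7 for independent groups, while genes of the same libraries are not independent. Itgax was at 357 CPM in CD11c+ replicate 1, against 198 to 212 in the other CD11c+ libraries. Anxa1 was at 21.7 CPM in CD11c+ replicate 3, against 3.52 to 6.24, and S100a8 at 153 CPM there, against 1.22 to 23.9. In CD11c+ replicate 2, Ifng was at 145 CPM (85.2 to 86.2 in the others) and Tox at 413 (220 to 250). CD11c- replicate 2 had higher Havcr2 (318 CPM against 193 to 207), Top2a (877 against 682 to 709) and Ccl3 (241 against 89.7 to 107), and lower Gas7 (312 against 366 to 370) and Tnfsf14 (19.3 against 24.8 to 25.1). Ifng (119 CPM) and Tox (586) were also highest in replicate 2 among CD11c- libraries. Among CD11c+ libraries Havcr2 (399), Top2a (1100) and Ccl3 (396) were highest in replicate 2 too. Replicate 2 was thus highest in both subsets for Ifng, Tox, Havcr2, Top2a and Ccl3. These genes were picked for an outlying replicate 2 in 1 subset, and whether they follow the other numbers was not tested. H2-Aa was at 19.4 CPM in CD11c- replicate 4, against 6.72 to 8.65. Cd4 was at 1.56 CPM in CD11c+ replicate 4 and at 0 in the other CD11c+ libraries. CD11c- replicate 1 had 10783 detected genes, against 12120 to 12322 in the other CD11c- libraries.

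The first pattern is the higher level of 8 NK receptor and granule genes (Klre1, Klrc1, Klrk1, Klrd1, Gzma, Gzmb, Gzmm, Serpinb9) in CD11c+ cells, with a median log2 fold change of 1.41. NK cells in the CD11c+ sort, which the NK1.1- and TCRβ+ gate would remove, would bring Tyrobp, yet its rise of 12.6 CPM (SE 11.8) was 10.3% of that of Klrk1 (122 CPM), and Ncr1 was at most 1.78 CPM in any library. A few NK cells cannot be excluded by these values, as 8 of 10 tested NK and ILC1 markers had positive log2 fold changes. Without the 3 libraries with the fewest detected genes the median was 1.71. The 8 genes were picked for their rise in all libraries and did not overlap between subsets, so a positive median was nearly fixed in advance. The value shows only that the median was no smaller without these 3 libraries. After removing the trend on transcript length and GC content the median was 1.31 (bootstrap SE 0.165, from resampling the 8 genes and not the libraries). Over all genes that trend was weak (rank correlation 0.124 with length and -0.118 with GC content). For genes picked for large changes in these libraries the test could therefore hardly come out otherwise. A candidate explanation is that CD11c marks effector cells with more of these transcripts, a hypothesis drawn from these same libraries and not tested here. Differences between mice or sort days stay open, as the labels name neither.

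The second pattern is Itgax together with 4 MHC class II transcripts (H2-Ab1, H2-Aa, H2-Eb1, Cd74) in CD11c+ cells. The MHC class II- and TCRβ+ gate would remove dendritic cells, if its staining was complete. Dendritic cells carry abundant Cst3, Tyrobp and Fcer1g, which the gate does not select on, but the sum of these was higher by 35.4 CPM (SE 36.8), 15.2% of the rise of Itgax (233 CPM), which argues against dendritic cells as the whole source of Itgax. For these 4 genes themselves a few dendritic cells cannot be told apart from expression in the T cells, as the summed level of 8 dendritic cell markers gave p = 0.257 in an exact permutation test. In CD11c+ replicates 1 to 4 this sum was 4.69, 4.37, 20.8 and 15.0 CPM, and H2-Ab1 was at 28.7, 39.3, 69.7 and 67.7 CPM. Among the 8 markers Xcr1 was at 3.51 CPM and 1.01 CPM in the 2 subsets. Irf8, an abundant transcript of dendritic cells that activated T cells also express, was at 190 and 188 CPM.

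The third pattern is a set of small shifts of large lists, G2 and M phase genes higher and ribosomal protein genes lower. Without the trend on length and GC content the medians were 0.20 (bootstrap SE 0.0352) and -0.107 (bootstrap SE 0.0172), against 0.20 and -0.134 before. Removing the trend left most of each median, which argues against such a trend as their whole cause. These SE come from resampling the genes of a list as if independent. They do not measure the spread between libraries, and camera called neither list with an estimated correlation. The G2 and M phase median was at least 0.152 whichever library was left out, so it does not rest on 1 library, but without the 3 libraries with the fewest detected genes the medians were 0.10 and 0.03, so the lower ribosomal protein genes were not seen without them. For the count of 5 genes past the threshold, 1 of 35 splits (the real one) gave as many. The highest of the others gave 1. This argues against chance only if the libraries can be exchanged freely. That may not hold, as libraries of numbers 2, 3 and 4 correlated best with their own number. The share is the smallest that 35 splits can give, and the count includes Itgax, the gene of the sorted protein. Chance is not excluded for each gene, as Id2, Ly6c2 and Cxcr5 lost the threshold in most fits without 1 library. For the number of lists called chance cannot be excluded, as 4 of 35 splits gave at least 12 and the highest of the others gave 18.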

How the results depend on the processing

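Itgax kept its direction and its call in every setting run, with log2 fold changes of 4.31 to 5.10. Numbers of calls moved more, while every named gene past the threshold kept its direction; the cause was not tested unless given. Against 3 genes higher and 2 lower, there were 10 higher without a filter and 6 with the stricter one (fewer genes tested), 24 and 12 with DESeq2, 14 and 5 with limma voom, 1 and 0 against a 1.5-fold change, and 1 and 0 at a threshold of 0.01. Among settings chosen after seeing the data, legacy=FALSE gave 9 higher and the fit without the 3 libraries with the fewest detected genes 9 higher. All 5 genes were also called by DESeq2, limma voom, legacy=FALSE and the fit with the replicate block.

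With the replicate block there were 11 genes higher (also Ccr2, Gzma, Gzmb, Klrc1, Klrd1, Klre1, Klrk1 and Ly6a) and 19 lists called, the 12 and those of cytokines and chemokines, heat shock, MHC class II and dendritic cell markers (higher) and of inhibitory receptors, type I interferon response and oxidative phosphorylation (lower). Libraries of the same number correlated at 0.0643, 0.23, 0.143 and 0.217 (deviations from subset means over 8175 genes), and those of numbers 2, 3 and 4 but not 1 correlated best with their own number, a hint from the data and not the design. The 12 lists called became 0 with an estimated correlation and 1 with the directional fry test (20 with its mixed test, which asks for change in either direction).

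Leaving out 1 library, or 1 number with the replicate block, gave 1 to 12 genes higher, 0 to 5 lower and 9 to 17 lists, and the ribosomal protein, fatty acid oxidation, monocyte, NK and ILC1 and CD4 lists each lost their call in some of these fits. Genes without a call that changed sign in other settings than leaving out 1 library or number were Tnfrsf9 (log2 fold change 0.000546 with RLE factors, 0.00234 with library size only and 0.000933 with DESeq2, against -0.000139) and Cd3e (-0.015 with limma voom and -0.025 without the 3 libraries). Over the fits that leave out 1 library or number Tnfrsf9 ran from -0.21 to 0.21, Cd3e from -0.026 to 0.076, Lyz2 from -0.34 to 0.87 and S100a8 from -0.86 to 1.52, while without the 3 libraries Tnfrsf9 was at -0.36 and Lyz2 at 1.19.

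In simulated data 4-fold changes were recovered in 77.4% and 1.5-fold changes in 6.21% of cases, and recovery by expression level was not tested.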

Other observations

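Several gene groups of activated T cells were not called by camera. Of 37 tested type I interferon response genes 24 had negative log2 fold changes, and camera did not call them (adjusted p = 0.0822), but called them lower without CD11c+ replicate 1 (adjusted p = 0.00458), CD11c- replicate 2 (adjusted p = 0.0184) or the 3 libraries with the fewest detected genes (adjusted p = 0.0407). Of 45 oxidative phosphorylation genes 33 were negative (adjusted p = 0.0662), and they were called lower with the stricter filter (adjusted p = 0.0298) and in 5 of the 8 fits without 1 library. Of 21 glycolysis genes 13 were positive (adjusted p = 0.478). Immediate early and T cell receptor induced genes (27 tested, adjusted p = 0.453), NF-kB targets (20 tested, adjusted p = 0.601) and tissue residency genes (16 tested, adjusted p = 0.295) were not called. In these 6 lists 0 genes passed over all genes by edgeR's quasi-likelihood test, and those with an unadjusted p under 0.05 numbered 2, 1, 2, 3, 0 and 3 in the order given. Xcl1, a residency gene, alone rose adjusted over the list alone, and it alone was called by DESeq2, with 0 called by limma voom.

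Genes outside the lists also set the subsets apart when other tools were used, chosen here after their values were seen. DESeq2 and limma voom with quality weights both called 19 genes, 14 higher and 5 lower in CD11c+ cells. Besides the genes already described these were Zmiz1, a transcriptional coregulator (1.67-fold higher, 154 CPM ± 2.12 against 92.0 ± 7.55), Ly6a, which encodes Sca-1 (2.08-fold, 374 ± 108 against 180 ± 42.4), Plac8 (2.08-fold, 98.2 ± 28.4 against 47.2 ± 12.1), and, lower, Gas7 (221 ± 37.3 against 354 ± 27.7). By edgeR's quasi-likelihood test their adjusted p were 0.0677, 0.146, 0.401 and 0.153, and in each case the 4 libraries of one subset lay above the 4 of the other. Bmp7, a secreted growth factor, was 2.59-fold lower in CD11c+ cells (12.9 CPM ± 1.88 against 33.5 ± 4.87, adjusted p = 0.107), also without overlap. Without overlap between the subsets were 3.45% of the tested genes, where chance gives 2.86%.

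Over all tested genes the log2 fold change had a rank correlation of 0.124 with transcript length and -0.118 with GC content, across genes, which are not independent replicates. Quality weights from limma voom ran from 0.414 for CD11c+ replicate 1 to 2.08 for CD11c- replicate 3.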
